A study of Mus musculus with 6 samples.

How the data were processed

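Gene expression was measured by sequencing of polyadenylated RNA from primary mouse hepatic stellate cells, the vitamin A-storing pericytes of the liver. Per the labels' protocols, the cells came from female C57BL/6JBomTac mice. At 2 days after isolation they received 5 µM forskolin, a plant diterpene that activates adenylyl cyclase and so raises cyclic AMP, or the same volume of the vehicle dimethyl sulfoxide (diluted 1:1000). The medium was changed after 3 h and RNA was taken after a further 21 h, that is 24 h after the start. Libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols, which do not state that strand was kept. There were 3 libraries per group, named by the replicate letters A, B and C. The labels do not say whether these came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

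The authors deposited 1 table of unnormalized estimated counts per gene, with 24940 rows, 1 RefSeq transcript per gene symbol and the exon length of each. Per the submitters' processing notes, STAR and HOMER were used with the mouse build mm10. Their versions and settings, and the annotation release, are not given in the sources used here. The deposited values are all multiples of 0.5, and 31.8% of them are not whole, so they were treated as estimated counts that need not be whole (the kind called expected counts) and rounded to whole numbers before any test. Why values in steps of 0.5 occur is not stated. Coordinates are those of the deposited table on mm10. They count from 1, since 15737 of the 24224 rows found on the same chromosome of a RefSeq annotation of GRCm38 had an identical start and 9 had a start lower by 1.

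Column totals of the deposited counts were 10890193, 12954310 and 12009289.5 for forskolin A, B and C, and 13729745.5, 15090262.5 and 13001358 for vehicle A, B and C. With edgeR 4.0.16 in R 4.3.3, genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13357 genes holding 99.9% of all counts. Libraries were scaled with TMM factors. Forskolin was compared with vehicle by the quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The biological coefficient of variation was 4.44%. Levels are given as CPM, the usual library-scaled count, computed on TMM-scaled library sizes, as mean ± SD over 3 libraries. Log2 fold changes are forskolin over vehicle, with a standard error (SE) obtained from the quasi-likelihood F statistic. For leading genes with few counts in 1 group, the ratio of the pooled counts is given with an exact 95% binomial (Clopper-Pearson) interval, which covers counting error only.

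In all, 26 gene lists were fixed before the data were examined: the response to cyclic AMP, the cyclic AMP signalling machinery, G protein-coupled receptors, quiescent stellate cell markers, retinoid genes, contractile genes, structural matrix, basement membrane, matrix enzymes, TGF-beta genes, YAP and TEAD targets, cell cycle, inflammatory genes, interferon response, cholesterol synthesis, lipid droplet genes, growth factors, endoplasmic reticulum stress with ATF4 targets, oxidative stress, and markers of macrophages, sinusoidal endothelium, hepatocytes, cholangiocytes, lymphocytes, mesothelium with portal fibroblasts, and vascular smooth muscle. Lists with at least 3 tested members were compared with all other genes by camera from limma 3.58.1 (preset correlation 0.01), and again with an estimated correlation. The self-contained test fry was also run. List p-values were adjusted over the 25 lists tested. The genes named were also chosen by a rule set in advance. It takes the 10 genes that rose and the 10 that fell most among those past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted gene models. It adds up to 3 members of each list with the smallest adjusted p, and 11 genes named in advance (Crem, Nr4a1, Pde4d, Lrat, Acta2, Col1a1, Col1a2, Col3a1, Timp1, Pdgfrb and Des). Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen.

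The fit was tested on simulated counts drawn for the same 13357 genes with the means, library sizes and dispersions of these libraries, of which 200 were changed. For this comparison edgeR recovered 42% of the genes changed by 1.25-fold, 78% at 1.5-fold, 100% at 2-fold and 98% at 4-fold, with 15 calls among the unchanged genes. In the data 49.9% of genes passed, far more than were changed here. With fewer changed genes the adjusted threshold asks for a smaller p-value, so recovery in the data can differ. TMM scaling was not tested with so many genes changed. Among the 25 lists, camera called 0 when no list was shifted, and it called a list shifted by 0.5 on the log2 scale. In simulated counts the genes of a list vary independently, so this does not test the preset correlation.

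Alternatives were DESeq2 size factors within the edgeR fit, library size without TMM, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate letter as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, a threshold of 0.01, a test against a 1.5-fold change, and for the lists an estimated correlation, fry and the removal of shared members. Further alternatives were added after the data were seen: genes with over 1 count per base of exon were left out, and library size was added as a covariate. Testing several rows per symbol was not run, because each symbol had 1 row.

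The share of each named gene's 50-base stretches that no other GENCODE M21 gene holds, on either strand, was computed from the annotated transcripts, together with exon overlap. Of 97 named genes, 77 had at least 95% unique stretches. Counts of the others are uncertain where the authors' counting could split or drop shared reads. Among these were Hsd3b6 (84.3%), Cd55 (90.9%), Lce1g (82.2%), Lce1h (80.1%), Lce1l (90.3%), Lyz2 (84.6%) and Ass1 (61.4%), which resemble other sequences, and 10 genes with over 10% of their exonic bases shared with an overlapping gene, such as Trf (63.5%), Rarb (38.4%), Vcl (25.5%) and Ccnd1 (23.4%).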

Results

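Polyadenylated RNA was sequenced from primary mouse hepatic stellate cells, the vitamin A-storing pericytes of the liver, in 3 libraries after forskolin and 3 after vehicle. Forskolin activates adenylyl cyclase and so raises cyclic AMP, the second messenger of receptors coupled to stimulatory G proteins. The cells had been exposed to 5 µM forskolin for 3 h and were collected 21 h after it was removed. The comparison addressed which genes of stellate cells differ a day after a short pulse of cyclic AMP signalling. Total counts per library ranged from 10890193 to 12954310 with forskolin and from 13001358 to 15090262.5 with vehicle, so the vehicle libraries were the deeper ones. Log2 CPM correlated across genes with Pearson's r of 0.990 to 0.995 within groups and 0.965 to 0.969 between groups, genes not being independent replicates. The first principal component of the 500 genes most variable over these 6 libraries held 90.8% of their variance and separated the groups. As the genes were chosen by their variance in the same libraries, this separation is no independent test of a group difference.

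The cytokine gene Il11 rose 84.9-fold, from 3.93 ± 0.520 CPM with vehicle to 337 ± 13.5 CPM with forskolin (SD, n = 3 each), and the collagenase gene Mmp13 fell from 389 ± 11.3 to 36.1 ± 9.90 CPM. Of 13357 genes tested, 3319 rose and 3349 fell (edgeR, adjusted p under 0.05), together 6668 or 49.9%. With library size alone in place of TMM scaling, 3988 rose and 2874 fell, 58.1% of these genes being higher against 49.8% with TMM. Most changes were small, with a median absolute log2 fold change of 0.40 among these genes, and 884 genes changed at least 2-fold, of which 388 rose and 496 fell. The groups did not overlap for 7634 genes (57.2%, against 10% by chance for 3 against 3). With library size as a covariate, an alternative chosen after the data were seen, the number of genes past the threshold was 4297. Tested against a 1.5-fold change instead of no change, it was 1000.

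**Figure D1:**
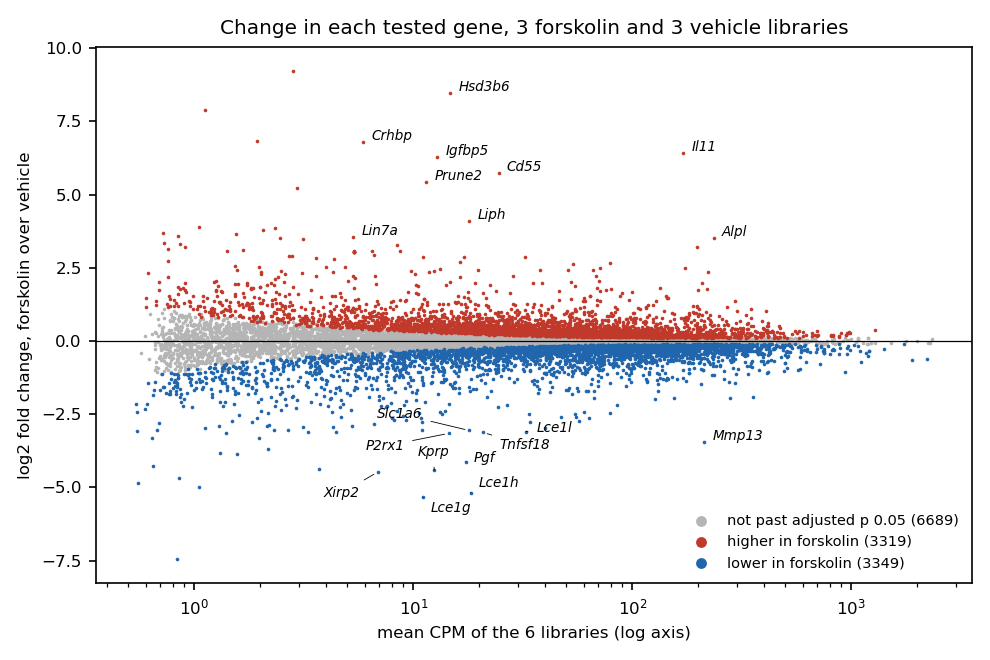
Each point is 1 of 13357 tested genes, with the mean CPM of the 6 libraries on the horizontal log axis and the log2 fold change of forskolin over vehicle on the vertical axis. Red points (3319 genes) were higher and blue points (3349 genes) lower in forskolin at an adjusted p under 0.05 in edgeR, grey points did not pass, and names mark 9 leading genes that rose and 10 that fell.

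Among the leading genes, Il11 (mm10 chromosome 7, 4772378 to 4778141) had a log2 fold change of 6.41 (SE 0.0749, edgeR adjusted p = 1.19e-20), and Alpl (chromosome 4, 137741731 to 137796384), which encodes the tissue-nonspecific alkaline phosphatase, rose 11.4-fold from 37.7 ± 5.89 to 433 ± 62.7 CPM (adjusted p = 7.92e-15). Several leading genes were almost uncounted with vehicle. The steroid dehydrogenase gene Hsd3b6 (chromosome 3, 98805504 to 98814443) went from 3 counts over the 3 vehicle libraries to 29.3 ± 4.46 CPM with forskolin, a ratio of 406 with a 95% counting interval of 138 to 1970. Crhbp (chromosome 13, 95431376 to 95444831), which encodes a binding protein of corticotropin-releasing hormone, had 4 counts with vehicle and 11.7 ± 0.812 CPM with forskolin, a ratio of 120 (95% counting interval 46.6 to 443). Igfbp5, an insulin-like growth factor binding protein gene, went from 0.332 ± 0.396 to 25.4 ± 4.88 CPM, a ratio of 80.5 (95% counting interval 46.9 to 152). These intervals cover counting error only. Igfbp5 had 1, 2 and 10.5 counts in vehicle A, B and C, and without vehicle C its fitted log2 fold change was 7.79 in place of 6.29. For Hsd3b6 vehicle C held 2 of the 3 counts, and without it the fitted log2 fold change was 9.36 in place of 8.48. Cd55, a complement regulator gene, rose from 0.896 to 48.1 CPM. Prune2 went from 0.502 to 22.4 CPM, a ratio of 44.1 (95% counting interval 28.7 to 71.7). Liph rose from 1.95 to 34.0 CPM and Lin7a from 0.819 to 9.79 CPM. The counts of Hsd3b6 and Cd55 are uncertain, with 84.3% and 90.9% of their 50-base stretches found in no other gene.

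Mmp13 (chromosome 9, 7272514 to 7283333) fell by 3.44 on the log2 scale (SE 0.101, edgeR adjusted p = 1.39e-14). Pgf (chromosome 12, 85166639 to 85177313), which encodes placental growth factor, went from 32.8 ± 1.18 to 1.90 ± 0.498 CPM and fell by 4.12 (adjusted p = 8.5e-14). Of the 10 genes that fell most, 4 were neighbours on chromosome 3 in the epidermal differentiation complex, a cluster of genes for proteins of the cornified skin layer. Lce1g fell from 21.5 to 0.540 CPM, a ratio of vehicle over forskolin of 41.1 (95% counting interval 26.1 to 68.5), Lce1h from 35.5 to 1.01 CPM, Kprp from 23.8 to 1.13 CPM and Lce1l from 58.2 to 7.02 CPM. Without forskolin A the log2 fold change of Lce1h was -5.98 in place of -5.19. Lce1g, Lce1h and Lce1l share 50-base stretches with other genes (82.2%, 80.1% and 90.3% unique), so their separate counts are uncertain. Taken here as the genes that start between S100a8 and S100a11, the complex had 11 tested genes. S100 genes at or beyond these bounds were not counted. The 11 genes were chosen for description after their values were seen, and 10 were lower and Sprr2g was higher. The other genes that fell most were Xirp2, an actin-binding protein gene of muscle (13.1 to 0.596 CPM, a ratio of vehicle over forskolin of 22.7 with a 95% counting interval of 14.7 to 36.9), the ATP-gated channel gene P2rx1 (26.0 to 2.94 CPM), Tnfsf18, a tumour necrosis factor family ligand gene (37.4 to 4.32 CPM), and the glutamate transporter gene Slc1a6 (32.0 to 3.84 CPM).

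**Figure D2:**
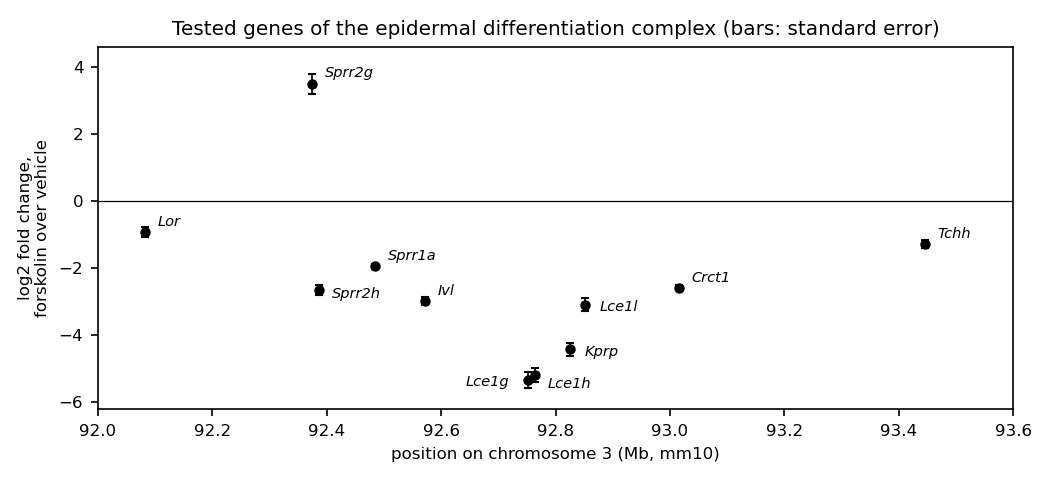
Log2 fold change of forskolin over vehicle (points, with SE as bars) for the 11 tested genes of the epidermal differentiation complex that start between S100a8 and S100a11, by position on chromosome 3 of mm10 in megabases. Of these genes 10 lie below 0, Lce1g lowest at -5.33, and Sprr2g lies above it at 3.50.

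Genes of the transcriptional response to cyclic AMP rose as a list, with 16 of 24 tested members higher and 5 lower. The repressor gene Crem rose from 21.0 ± 0.742 to 84.1 ± 1.6 CPM, the nuclear receptor gene Nr4a1 from 23.3 ± 1.58 to 86.5 ± 3.40 CPM (log2 fold change 1.89), and the cyclic AMP phosphodiesterase genes Pde4d from 10.1 to 46.8 CPM (2.21) and Pde4b from 59.7 to 207 CPM (1.80). Sik1, a kinase gene induced by cyclic AMP, rose by 1.48. The list passed camera (adjusted p = 1.79e-14, median log2 fold change 0.83), and it alone of the 25 tested lists also passed with an estimated correlation (adjusted p = 0.0224). Among genes that carry the signal itself, 11 of 36 rose and 11 fell, and the list did not pass (camera adjusted p = 0.57, median 0.03, mean -0.05). Prkar2b, a regulatory subunit gene of protein kinase A, rose from 70.2 to 166 CPM, while the anchoring protein gene Akap12 fell from 775 to 470 CPM and the kinase inhibitor gene Pkig from 64.9 to 41.5 CPM. Of 23 G protein-coupled receptor genes 8 rose and 9 fell (camera adjusted p = 0.26, median -0.10, mean 0.06, test direction up). The endothelin receptor gene Ednrb rose from 99.8 to 340 CPM and the angiotensin receptor gene Agtr1a from 104 to 200 CPM, and the adenosine receptor gene Adora2a fell from 75.6 to 23.9 CPM.

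Oxidative stress response genes rose as a list, 17 of 20 higher and 0 lower (camera adjusted p = 5.59e-18, median 0.56). With an estimated correlation the call was lost (adjusted p = 0.271 with an estimated correlation). The glutathione transferase gene Gsta4 rose from 27.7 to 113 CPM, the cystine transporter gene Slc7a11 from 83.2 ± 3.86 to 331 ± 55.1 CPM, and the quinone reductase gene Nqo1 from 146 to 288 CPM. The list of endoplasmic reticulum stress and ATF4 genes had 10 of 26 members higher and 14 lower. It passed camera in the upward direction (adjusted p = 0.0267; adjusted p = 0.669 with an estimated correlation), with a mean of 0.21 and a median of -0.15. Trib3, a pseudokinase gene induced by ATF4, rose from 20.5 ± 1.11 to 111 ± 10.1 CPM, the asparagine synthetase gene Asns from 115 to 264 CPM and the serine hydroxymethyltransferase gene Shmt2 from 126 to 251 CPM. Without forskolin A the list's adjusted p was 0.053, without vehicle B 0.0625, and with library size as a covariate 0.311.

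Genes of structural matrix fell as a list, 18 of 31 lower and 4 higher (camera adjusted p = 3.33e-05, median -0.25; adjusted p = 0.387 with an estimated correlation). Col8a1 fell from 109 ± 4.74 to 17.7 ± 3.84 CPM, Col12a1 from 1272 to 604 CPM and the matricellular protein gene Postn from 436 to 260 CPM. Col1a2 fell by 0.68 on the log2 scale and Col1a1 by 0.26, from 1540 ± 39.5 to 1285 ± 40.4 CPM (edgeR adjusted p = 6.02e-05). Col3a1 was at 1071 ± 33.4 and 980 ± 64.8 CPM (adjusted p = 0.0365), a call that was lost under 7 of the alternatives applied to named genes. Genes of matrix crosslinking and turnover also fell, 18 of 34 lower and 7 higher (camera adjusted p = 8.96e-05, median -0.30; adjusted p = 0.362 with an estimated correlation). Besides Mmp13, the aggrecanase gene Adamts5 fell from 139 to 47.7 CPM, while Plat, which encodes tissue plasminogen activator, rose from 52.5 to 294 CPM. Timp1, a metalloproteinase inhibitor gene, rose by 0.17 (adjusted p = 0.00655), a call lost with library size as a covariate. The 96 genes with over 3 counts per base of exon, Col1a1 among them, had a median log2 fold change of 0.07 in the shallower forskolin libraries. Without genes of over 1 count per base, an alternative chosen after the data were seen, the adjusted p of the enzyme list was 0.137. That setting also left out members of the list, Mmp13 among them (1.08 counts per base). The lost call therefore does not tell an effect of dense counting from the loss of these members.

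Basement membrane genes moved in both directions, 7 of 16 higher and 7 lower (camera adjusted p = 0.527, median -0.03, mean 0.01). Within the laminins Lama1 rose from 92.2 to 306 CPM and Lama2 fell from 93.5 to 28.7 CPM, and Col4a5 fell from 188 to 79.2 CPM. TGF-beta pathway and target genes had 8 of 29 members higher and 13 lower (camera adjusted p = 0.062, median -0.06). Ltbp2, a gene of the family named latent TGF-beta binding proteins, fell by 2.42 and Grem1 by 2.48. Without vehicle A the adjusted p of this list was 0.0283.

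Targets of YAP and TEAD, regulators that respond to mechanical tension, fell as a list, 20 of 26 lower and 3 higher (camera adjusted p = 1.68e-05, median -0.37; adjusted p = 0.362 with an estimated correlation). Amotl2 fell from 626 ± 8.71 to 368 ± 10.7 CPM and Gadd45b from 57.1 to 10.3 CPM, while Gadd45a rose from 33.0 to 85.8 CPM. Contractile and cytoskeletal genes of activated stellate cells had 13 of 26 members lower and 5 higher, and the list did not pass camera (adjusted p = 0.258, median -0.06). It passed, downward, without forskolin C (adjusted p = 0.0406) and without genes of over 1 count per base (0.0448), and with shared members left out its direction turned (0.78). Acta2, the smooth muscle actin gene used as a marker of activated stellate cells, fell by 0.18 on the log2 scale from 484 ± 12.8 to 427 ± 15.5 CPM (edgeR adjusted p = 0.00158). The intermediate filament gene Des fell by 0.83 from 323 to 182 CPM, Cnn1 by 1.06 and Vcl by 0.35, Vcl having 74.9% unique stretches. Vascular smooth muscle markers fell, 11 of 14 lower and 1 higher (camera adjusted p = 0.0119, median -0.45; adjusted p = 0.669 with an estimated correlation), with Actg2 going from 29.7 to 14.9 CPM. This list shares members such as Des and Cnn1 with the contractile list, and with shared members left out its adjusted p was 0.78. The platelet-derived growth factor receptor gene Pdgfrb fell from 381 to 282 CPM.

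Markers of quiescent stellate cells were split, 12 of 24 higher and 7 lower (camera adjusted p = 0.416, median 0.17). The growth factor gene Hgf rose from 198 to 401 CPM and the channel regulator gene Abcc9 from 123 to 272 CPM, and the transcription factor gene Tcf21 fell from 106 ± 2.32 to 27.3 ± 1.88 CPM. Lrat, which encodes the enzyme that esterifies retinol for storage, was at 55.0 ± 1.85 CPM with vehicle and 51.9 ± 9.09 CPM with forskolin (log2 fold change -0.08, edgeR adjusted p = 0.487). Of 17 retinoid genes 3 rose and 6 fell (camera adjusted p = 0.432, median -0.14). The retinoic acid hydroxylase gene Cyp26b1 fell by 0.86 and the retinoic acid receptor gene Rarb by 0.40, the latter overlapping Top2b, and the retinal reductase gene Dhrs3 rose by 0.49.

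Cell cycle genes fell as a list, 15 of 36 lower and 0 higher (camera adjusted p = 0.0288, median -0.25; adjusted p = 0.669 with an estimated correlation). The cyclin gene Ccnd1 fell by 0.57, the replication licensing gene Mcm3 by 0.50 and the ribonucleotide reductase gene Rrm1 by 0.55. Cholesterol synthesis and SREBP2 target genes fell, 17 of 25 lower and 1 higher (camera adjusted p = 0.00061, median -0.35; adjusted p = 0.669 with an estimated correlation), with Sc5d going from 112 to 66.9 CPM and Cyp51 from 121 to 86.3 CPM. Lipid droplet and adipogenic genes had 5 of 21 members higher and 9 lower (camera adjusted p = 0.326, median 0.01, mean -0.08). The lipoprotein lipase gene Lpl fell from 226 to 92.2 CPM and the fatty acid synthase gene Fasn from 513 to 319 CPM, and the transcription factor gene Cebpd rose from 66.6 to 145 CPM. The cell cycle call was lost without forskolin A (adjusted p = 0.192), without vehicle B (0.0603) and with library size as a covariate (0.724).

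Inflammatory cytokine and adhesion genes had 5 of 16 members higher and 10 lower (camera adjusted p = 0.233), with a median of -0.46 and a mean of 0.26. Besides Il11, the cytokine genes Il6 and Il33 rose, from 6.16 ± 0.725 to 33.4 ± 3.41 CPM and from 33.7 ± 2.34 to 109 ± 10.2 CPM. Interferon response genes had 14 of 24 members higher and 2 lower (camera adjusted p = 0.062, median 0.48). Isg15 rose from 17.2 to 31.3 CPM and Ifi35 from 20.3 to 33.2 CPM, and Ifit2 fell from 56.3 to 29.1 CPM. Without forskolin A the adjusted p of the interferon list was 0.0152, without vehicle C 0.0488 and with library size as a covariate 0.0204. Among growth factors and morphogens 12 of 32 rose and 13 fell (camera adjusted p = 0.464, median 0.06). Gdf2, which encodes bone morphogenetic protein 9, rose from 73.9 to 212 CPM and the Wnt signalling enhancer gene Rspo3 from 124 to 240 CPM.

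Of the markers of other cell types, liver sinusoidal endothelial markers fell as a list, 6 of 12 tested members lower and 1 higher (camera adjusted p = 0.0288, median -0.51; adjusted p = 0.362 with an estimated correlation), led by the vascular endothelial growth factor receptor genes Flt4 (195 ± 4.20 to 79.7 ± 1.42 CPM), Flt1 (27.9 to 8.54 CPM) and Kdr (3.21 to 1.08 CPM). With library size as a covariate the adjusted p of this list was 0.0621, and that of the vascular smooth muscle list 0.0669. Of 20 macrophage markers 5 were tested, of which Csf1r and Cd68 rose, from 13.2 to 18.3 and from 11.2 to 15.8 CPM, and Lyz2 fell from 10.8 to 4.23 CPM (camera adjusted p = 0.85, median 0.34, mean -0.04). The call of Cd68 was lost without forskolin B and that of Csf1r with library size as a covariate. Of 21 hepatocyte markers 3 were tested and 2 rose, Trf and Ass1 (camera adjusted p = 0.26, median 0.32), whose stretches were 40.6% and 61.4% unique, while Apoa2 was at 4.33 and 4.80 CPM (edgeR adjusted p = 0.494). Cholangiocyte markers had 1 of 5 higher, Sox9, and 2 lower, Krt19 and Tm4sf4 (camera adjusted p = 0.435, median -0.08). Of these, Tm4sf4 lost its call under 8 of the alternatives applied to named genes. Its log2 fold change was -1.76 without forskolin A in place of -1.13. Mesothelial and portal fibroblast markers had 3 of 10 higher and 4 lower (camera adjusted p = 0.643, median -0.39, mean 0.03), with Thy1 rising from 0.650 to 4.93 CPM and Cd34 from 3.86 to 19.6 CPM, and Krt19, also a member of this list, falling from 71.3 to 35.1 CPM. Of 16 lymphocyte markers, Trbc2 was not among the deposited gene symbols. None of the others had enough counts to be tested, and they summed to 0.75 CPM with vehicle.

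**Figure D3:**
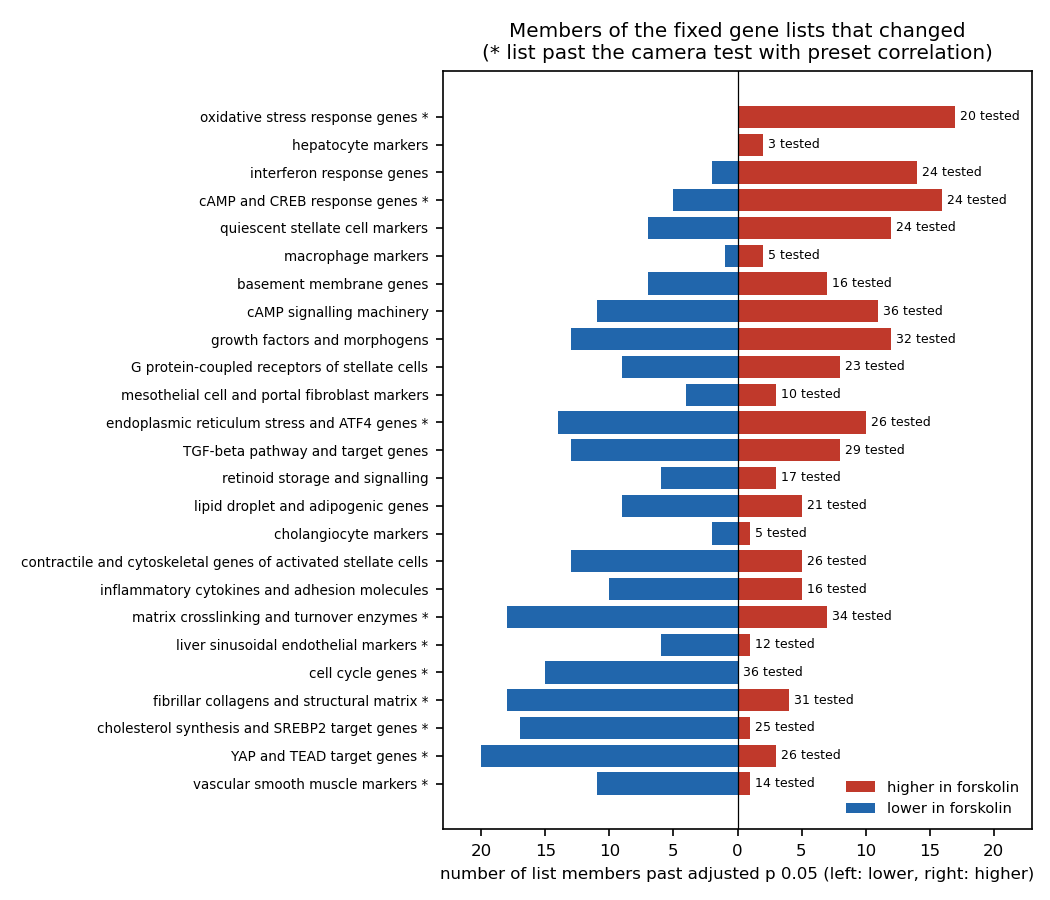
For each of the 25 tested lists, bars show the number of members past an adjusted p of 0.05 in edgeR that were lower (left, blue) or higher (right, red) in forskolin, and the text beside each bar gives the number tested. Asterisks mark the 10 lists past camera with the preset correlation, of which oxidative stress response genes had 17 members higher and YAP and TEAD target genes 20 lower.

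Adjusted over the list alone, the counts were the same as over all genes tested, except that 12 genes of cyclic AMP machinery, 7 retinoid, 20 matrix enzyme and 7 endothelial marker genes were lower, and 4 retinoid and 2 endothelial marker genes higher. In all, 10 of 25 lists passed camera with the preset correlation. Another division of the same 6 libraries, forskolin A, forskolin B and vehicle A against the rest, gave 13 lists past the same test and 0 genes past the threshold in edgeR. That division keeps part of the group difference in its contrast, so it gives no rate of false calls. Without TMM scaling no member past the threshold turned direction, but the counts of higher and lower members moved. They became 7 and 17 for structural matrix, 5 and 4 for retinoid genes, 9 and 11 for contractile genes, and 14 and 13 for growth factors. For quiescent markers they became 12 and 5, for TGF-beta genes 10 and 12, and for smooth muscle markers 1 and 9. In the other lists either count moved less.

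**Figure D4:**
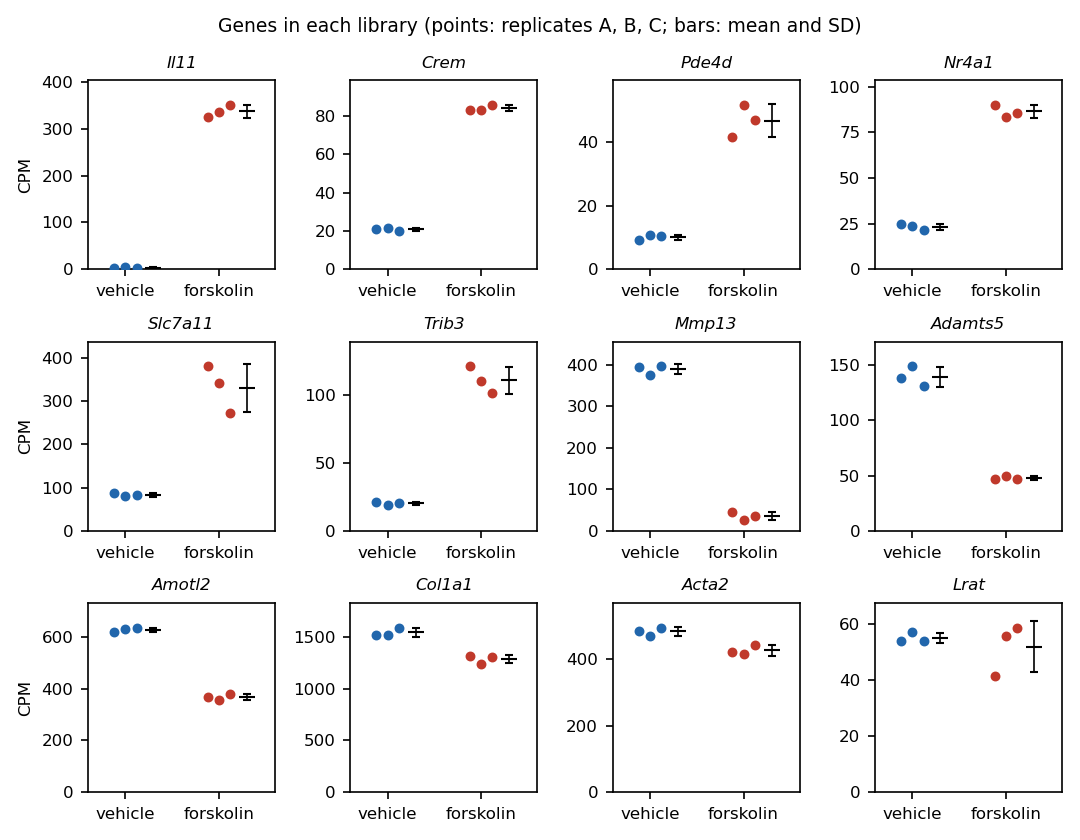
CPM of 12 genes in each library, with points for replicates A, B and C of vehicle (blue) and forskolin (red), and a bar with whiskers for the mean and SD (n = 3). The groups do not overlap for Il11, Crem, Pde4d, Nr4a1, Slc7a11, Trib3, Mmp13, Adamts5, Amotl2, Col1a1 and Acta2, and they overlap for Lrat.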

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

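Leaving out genes with over 1 count per base (1132 genes) and adding library size as a covariate were chosen only after the data were seen, and the other alternatives before. The number of changed genes, 6668, ranged from 5640 to 6800 when each library was left out in turn, and it was 5557 with DESeq2, 6667 with limma-voom, 6862 (3988 higher, 2874 lower) without TMM and 6930 without the filter. It fell to 4297 (1998 higher, 2299 lower) with the covariate, which takes a degree of freedom and part of the group difference, since forskolin libraries were shallower, and to 1000 (422 higher, 578 lower) in the test against a 1.5-fold change, a stricter question by construction. The letters A, B and C were not taken to pair libraries, because deviations from the group means correlated by only 0.0291, 0.0203 and 0.0377 between libraries of 1 letter. With the letter as a block 6675 genes changed, and in no list did the block end or add a call, although the basement membrane list, not past the threshold, turned direction (adjusted p = 0.988). The threshold of 0.01 and the test against a 1.5-fold change were applied only to the numbers of changed genes. With densely counted genes left out, 77 of the 97 named genes had a value. Of 1434 values of the 97 named genes under the settings applied to them, 1414 kept their direction and side of the threshold. The exceptions were Csf1r, Cd68, Tm4sf4, Col3a1, Timp1 and Lrat, the last turning to 0.054 without forskolin A (range over left-out libraries -0.17 to 0.054) and to 0.16 with the covariate. Of 399 list values 355 did so. With an estimated correlation only 1 list remained past the threshold in place of 10, and the adjusted p became 0.387 for structural matrix, 0.362 for matrix enzymes, YAP targets and endothelial markers, 0.271 for oxidative stress, and 0.669 for cell cycle, cholesterol synthesis, ATF4 genes and smooth muscle markers. There the correlation, estimated from 6 libraries, takes the place of the preset value, but this is not all that sets the outcome. The endothelial markers had an estimated correlation of 0.0021, below the preset 0.01, and still lost their call. A higher correlation between genes therefore does not account for that loss. The self-contained test fry, which asks another question, passed 15 lists, adding G protein-coupled receptors and hepatocyte markers (0.0259 each), TGF-beta genes (0.00115), interferon genes (0.0489), lipid genes (0.0469) and cholangiocyte markers (0.0106) and losing cell cycle (0.14). With the covariate the calls of cell cycle (0.724), ATF4 genes (0.311), endothelial markers (0.0621) and smooth muscle markers (0.0669) were lost, interferon genes passed (0.0204), and macrophage and mesothelial markers turned direction (0.923 each). Without densely counted genes, contractile (0.0448) and interferon genes (0.0312) passed, matrix enzymes (0.137) and smooth muscle markers (0.0513) did not, and basement membrane and inflammatory genes turned direction (0.816 each), fewer genes being tested. Without the filter TGF-beta and interferon genes passed (0.023 each). With shared members left out, smooth muscle markers lost their call (0.78), and contractile genes (0.78), cholangiocyte markers (0.91) and mesothelial markers (0.644) turned direction, fewer genes being tested. Over left-out libraries the adjusted p ranged from 0.0406 (without forskolin C) to 0.389 for contractile genes, from 0.0283 (without vehicle A) to 0.085 for TGF-beta genes, from 3.72e-05 to 0.192 (without forskolin A) for cell cycle genes, which also missed the threshold without vehicle B (0.0603), from 0.0152 (without forskolin A) to 0.19 for interferon genes, which also passed without vehicle C (0.0488), and from 0.0101 to 0.0625 (without vehicle B) for ATF4 genes, at 0.053 without forskolin A. Except where construction is named, the cause was not tested. Testing several rows per symbol was not run, because each symbol has 1 row. In simulated counts with these libraries' depth, number and dispersion, but with far fewer genes changed, 42% of the genes with the smallest change were recovered. The part that depth has in this was not tested.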

Other observations

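The tests of a ceiling on counts per base, of keratinocytes, of shared copies and of endothelial cells were chosen only after the result was seen. The genes named in this part fall outside the rule for named genes except Lce1g, Lce1h, Lce1l, Kprp, Flt4, Flt1 and Kdr, and were chosen after their values were seen. Within the list of endoplasmic reticulum stress and ATF4 genes, 10 of 26 members rose and 14 fell. Those that rose included Chac1 from 13.5 ± 1.45 to 41.6 ± 2.36 CPM (log2 fold change 1.62), Mthfd2 from 74.9 to 174 CPM (1.21), Phgdh from 71.9 to 159 CPM (1.14), Psat1 from 220 to 325 CPM (0.56) and Atf4 itself from 178 to 279 CPM (0.65). The transcription factor gene Xbp1 also rose, by 0.17 on the log2 scale. Among those that fell, the chaperone gene Hspa5 fell by 0.26, Dnajc3 by 0.44, Creld2 by 0.68, Pdia4 by 0.36 and the sensor gene Atf6 by 0.58, from 246 ± 7.75 to 165 ± 10.2 CPM. Sesn2, an ATF4 target, also fell, from 99.2 to 70.5 CPM, and the folding genes Pdia3 (edgeR adjusted p = 0.196) and Manf (0.16) did not pass. No division of this list was fixed in advance, so none was tested.

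Transcripts of the epidermal differentiation complex were counted in the vehicle libraries, and most fell with forskolin. Beside Lce1g, Lce1h, Lce1l and Kprp, the cornified envelope gene Sprr1a went from 245 ± 8.44 to 64.3 ± 10.9 CPM, the involucrin gene Ivl from 70.6 ± 1.40 to 9.05 ± 2.50 CPM and Crct1 from 80.9 ± 5.05 to 13.6 ± 1.29 CPM (SD, n = 3), all lower in edgeR. Sprr2h fell by 2.64, Tchh by 1.29 and Lor by 0.92 on the log2 scale, while Sprr2g rose from 0.388 to 4.51 CPM. The window of 10 neighbouring tested genes with the most genes lower by at least a doubling held 9 and lay here (chromosome 3, 92373915 to 93449077, from Sprr2g to Tchh), where 0 of 1000 shuffles of genes over positions reached 9 and the highest reached 6. The shuffles treat genes as separate, although the 9 include Lce1g, Lce1h and Lce1l, whose separate counts are uncertain. Among genes of the complex with at least 95% unique stretches, 6 were lower by at least a doubling, no more than the highest shuffle reached. Keratinocytes in the vehicle cultures are argued against by their keratins, as Krt5, Krt14, Krt1 and Krt10 together stayed at or under 2.08% of the level of Sprr1a in each vehicle library. Over all libraries Krt5, Krt14 and Krt1 had 1, 0.5 and 3 counts, and Krt10, which made up most of that sum, had 284.5. Reads shared between near-identical copies are argued against as the whole cause by the 8 genes of the complex with at least 95% unique stretches, whose median log2 fold change was -2.26. A response of this locus in stellate cells to forskolin is a candidate explanation that remains, as a hypothesis found on these data and not itself tested. The tests above used the same data and concern other explanations only.

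The receptor genes Flt4, Flt1 and Kdr, used as endothelial markers, fell with forskolin, and Egfl7 was at 18.2 ± 1.70 CPM with vehicle and 21.2 ± 0.736 CPM with forskolin (edgeR adjusted p = 0.0667), while Stab2 rose from 0.978 to 2.50 CPM. Eng, of the same list, was above Flt4, at 750 ± 26.1 CPM with vehicle and 699 ± 32.3 CPM with forskolin (adjusted p = 0.0652). Fewer endothelial cells in the forskolin cultures would need their abundant transcripts together in vehicle at a level like that of Flt4, and Eng alone does not tell them from other cells. Pecam1, Cdh5 and Emcn together reached at most 0.571% of Flt4 in any vehicle library, Emcn having 0 counts. As far as these genes mark endothelial cells, this argues against that explanation for Flt4. Egfl7, named beside them when the test was set, was left out of that sum. At 18.2 CPM with vehicle against 195 CPM for Flt4, Egfl7 was closer to Flt4 than they were, and it did not fall. Expression of Flt4 by the stellate cells themselves may then account for its fall, a hypothesis that was not tested further.

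Genes with many counts per base of exon read lower in the deeper libraries of a group. Among genes of 2000 to 8000 counts, the median slope of log2 CPM on log2 depth within groups was lower for 194 genes with over 2 counts per base than for 611 genes with under 0.75 (difference -0.33, 95% bootstrap interval over genes -0.367 to -0.30). The interval resamples genes only and leaves out the spread between the 6 libraries, on which every slope rests. A ceiling on reads counted per base, such as removal of reads with equal positions, would give such a difference, but no source used here states one. Within this range of counts, genes with more counts per base also tend to have a shorter exon length. The comparison therefore cannot tell a ceiling from an effect of length. Whether the lower depth of the forskolin libraries accounts for the group difference of these genes stays open: 96 genes with over 3 counts per base had a median log2 fold change of 0.07 over the 6 libraries and -0.0386 between forskolin B and vehicle C, whose depths differed by 0.362%, but this is a single pair with no spread between libraries, in which genes with under 0.1 counts per base also shifted, by 0.04. A share of counts taken by abundant genes stays open, since the slope of the sparse genes differed from that of 2403 genes of 50 to 200 counts by -0.0986, with an interval (-0.138 to -0.0317, again over genes only) that spans the bound set in advance.

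The 6 libraries can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real division gave 6668 changed genes and the highest of the others 0, so that 1 of the 10 gave as many. For the gene lists the real division gave 10 past camera and the highest of the others 13, so that 2 of the 10 gave as many. Every other division sets 2 libraries of 1 group with 1 of the other. Part of the group difference thus stays in its contrast, and the rest widens the spread within each side. The counts of the other divisions therefore give no rate of false calls.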
